A study of Mus musculus with 12 samples.

How the data were processed

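Total RNA of progenitor B cells from embryonic fetal liver was read on 12 single-colour Illumina mouse bead arrays with 45281 probes, 3 arrays for each of 4 groups, per the labels. The loss experiment held Sox4fl/fl and Sox4fl/fl SE-Cre cells, and the gain experiment held SE-Cre cells immortalized with p190 Bcr-Abl and labelled HA or HA-Sox4. The authors deposited a table of non-normalized intensities, linear and not background-subtracted by their values, 1 per probe and array. The same table holds a detection p-value for each intensity, which the authors deposited beside it, per the file headers. The authors also deposited a table of processed intensities. There, 99.97% (loss) and 99.96% (gain) of the values lay within 0.01 of the mean of the sorted non-normalized intensities of the 6 arrays of the experiment, which is quantile normalization within each experiment, with medians of 86.41 and 128.25. R 3.0.1 was used, per the submitters' processing notes, which give it no role. The scanner software and the summarization of beads were not given in the sources used here. Each processed column ranked the probes as its own non-normalized column did (lowest rank correlation 1.0), and no 2 arrays were identical.

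The non-normalized intensities were background-corrected, given an offset of 16, quantile-normalized and taken to log2 with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values, separately for each experiment. A probe was kept where its detection p-value was under 0.05 on at least 3 of the 6 arrays. The group means were compared with lmFit and eBayes, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Of all probes, 34885 carried 1 gene symbol, 18 carried several and 10378 carried none, and the symbols stood for 19057 genes. A gene was represented by its brightest kept probe. Where a group was detected on none of its 3 arrays, the fold is given as "at least": values of that group below the lowest signal of any detected probe on the same array were raised to that signal before the means were compared. The residual SD had a median of 0.19 in the loss and 0.143 in the gain experiment. The 3 arrays per group limit the precision, and dim probes are limited further by signal over background.

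For the difference between experiments, all 12 arrays were normalized and fitted together, and the HA-Sox4 minus HA difference was compared with the Sox4fl/fl minus SE-Cre difference over probes detected on at least 3 of 12 arrays. For genes past the threshold in both experiments, counts by direction were set against those of independent lists, and directions were compared with Fisher's exact test. The 24 gene lists, with 348 members of which 316 were on the array, were tested with camera of limma at a preset inter-gene correlation of 0.01 where at least 5 genes were kept, with p-values adjusted over the 44 tests of both experiments, and again with an estimated correlation. The lists covered V(D)J recombination, the pre-B cell receptor, B lineage transcription factors, pro-B and pre-B surface markers, mature B cell markers, Wnt targets, casein kinase 1 and the Wnt core, SoxC genes, cell cycle, p53 targets, the BCL2 family, cytokine and STAT5 targets, interferon response, immediate early and heat shock genes, the integrated stress response, glycolysis and hypoxia, cholesterol biosynthesis, reference genes, and markers of myeloid, mast and megakaryocyte, erythroid, T and NK, hepatocyte and stromal, and dendritic cells.

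The comparisons, thresholds, lists, alternatives and the rule for naming genes were chosen before the data were examined. Named were Sox4, Rag1, Rag2 and Csnk1e; in each experiment the 12 largest rises and falls past the threshold whose 3 values of a group all lay above the 3 of the other, an order that chance gives 10% of genes; up to 4 members of each list, those with the smallest p; and up to 10 genes in each class of direction over both experiments. Of the largest rises on loss, 1 gene is not reported here. The alternatives were no background correction, the authors' processed values, no detection filter, detection on every array, normalization or fitting of all 12 arrays together, eBayes with trend and robust, array weights, the replicate number as a block, each array left out, scaling to a common median, a limit of 1.5-fold, an estimated inter-gene correlation, the mean of a gene's probes, and the correlation over changed genes only. The SoxC list without Sox4 and the scaling of each named gene were added later. A block for slide or scan was not run, as the files give none.

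The fits were tested on simulated intensities with 200 changed genes. In the data more genes passed, 1469 on loss and 4085 on gain, which loosens the adjustment. The recovered shares may therefore be too low for the data. At 1.5-fold, 2-fold and 4-fold, 1.5%, 50.7% and 74.2% of changed genes were recovered in the loss design with 4 false calls, and 26.9%, 77.6% and 81.8% in the gain design with 19. For the difference between experiments 9%, 32.8% and 75.8% were recovered with 9 false calls. A list shifted 1.5-fold was called (adjusted p = 5.32e-25 and 1.11e-29) with 0 other lists, and data with no change gave 0 calls. The simulated noise was independent between probes, so this cannot test list calls where the genes of a list vary together. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. Probes without a symbol were tested but not named, and genes with no kept probe were not analysed here.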

Results

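Gene expression was measured in progenitor B cells from mouse fetal liver on 12 single-colour Illumina bead arrays, each read with 45281 probes. The samples made up 4 groups of 3 arrays and belonged to 2 experiments. The loss experiment compared cells with a floxed Sox4 gene (Sox4fl/fl) with Sox4fl/fl SE-Cre cells. No group carried SE-Cre with an intact Sox4 gene, so in that experiment effects of SE-Cre itself cannot be told apart from loss of Sox4. The gain experiment used Sox4fl/fl SE-Cre cells immortalized with p190 Bcr-Abl, an oncogenic tyrosine kinase fusion, and compared cells labelled HA with cells labelled HA-Sox4. Sox4 is a transcription factor of the SoxC group, and the series title named the Rag genes and the casein kinase gene Csnk1e as parts of its program in these cells. Median probe intensity was between 83.4 and 90.2 in the loss arrays and between 114.5 and 139.2 in the gain arrays, and between 36.1% and 40% of probes were detected on each array. Pearson correlations between arrays, taken across probes, which are not independent replicates, were between 0.993 and 0.996 within groups, between 0.975 and 0.984 for the other group of the same experiment, and between 0.941 and 0.958 across experiments. The labels do not say whether the 3 samples of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

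Sox4 itself was examined first, as a check of the labels. In the loss experiment its brighter probe fell from 10.61 ± 0.06 (SD, n = 3, log2 normalized intensity) in Sox4fl/fl cells to 4.50 ± 0.21 (SD, n = 3) in SE-Cre cells. The log2 difference was -6.10 (SE 0.15, adjusted p = 3.64e-10), or -3.97 without background correction and -4.20 with the authors' processed values. The probe was detected on 3 of 3 Sox4fl/fl and 1 of 3 SE-Cre arrays, so the size of the fall depends on the background. In the gain experiment the same probe was at 4.68 ± 0.28 (SD, n = 3) in HA cells, where no array detected it, and at 5.47 ± 0.43 (SD, n = 3) in HA-Sox4 cells, where 3 of 3 did. That rise was at least 1.18-fold (fitted log2 difference 0.79, SE 0.24, adjusted p = 0.0326). Without background correction the log2 difference was 0.26 (adjusted p = 0.0105), and with the authors' processed values it was 0.30 (adjusted p = 0.00853). Folds of other genes also depend on that correction. The other Sox4 probe was too dim to be kept in either experiment and was not tested. It read 4.65, 4.43 and 5.16 on the Sox4fl/fl arrays, 2 of which detected it, and 4.34, 4.16 and 4.23 on the SE-Cre arrays, where none did. It was not detected on any gain array and read 4.79, 4.57 and 5.04 in HA cells and 4.69, 4.76 and 4.75 in HA-Sox4 cells, so the rise was seen with 1 of 2 probes. That rise lost significance without HA replicate 1 (adjusted p = 0.0892) or without HA replicate 3 (adjusted p = 0.0906), or with no detection filter (adjusted p = 0.0615). Where either probe lies in the Sox4 transcript was not given in the sources used here, so the brighter probe's reading in HA-Sox4 cells does not measure an introduced copy that lacks the probed part. In SE-Cre cells its fall shows that most RNA with the probed part was lost, but not whether other parts remained.

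Rag1 and Rag2, which encode the recombinase that cuts antigen receptor genes, and Csnk1e, which encodes casein kinase 1 epsilon, were lower in SE-Cre than in Sox4fl/fl cells and lower in HA than in HA-Sox4 cells. Rag1 fell from 8.82 ± 0.38 (SD, n = 3) to 5.36 ± 0.41 (SD, n = 3) on Sox4 loss (log2 difference -3.47, SE 0.23, adjusted p = 5.2e-07) and was 18.7-fold higher in HA-Sox4 than in HA cells (log2 difference 4.23, SE 0.15, adjusted p = 2.11e-06). Rag2 was a dim probe. It was detected on 3 of 3 Sox4fl/fl arrays and on no SE-Cre array, a difference of at least 1.51-fold (adjusted p = 0.000351), and on no HA array but 3 of 3 HA-Sox4 arrays, at least 1.56-fold higher in the latter (adjusted p = 0.00742). Csnk1e was at least 4.26-fold lower in SE-Cre than in Sox4fl/fl cells (adjusted p = 5.86e-07) and at least 54.3-fold higher in HA-Sox4 than in HA cells (adjusted p = 8.61e-08), and its 2 probes moved alike in each experiment. Csnk1e and Rag2 were not detected in SE-Cre or in HA cells, so how far their differences differed between the experiments was not measured. For Rag1 that difference did not pass the test (adjusted p = 0.227).

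**Figure D1:**
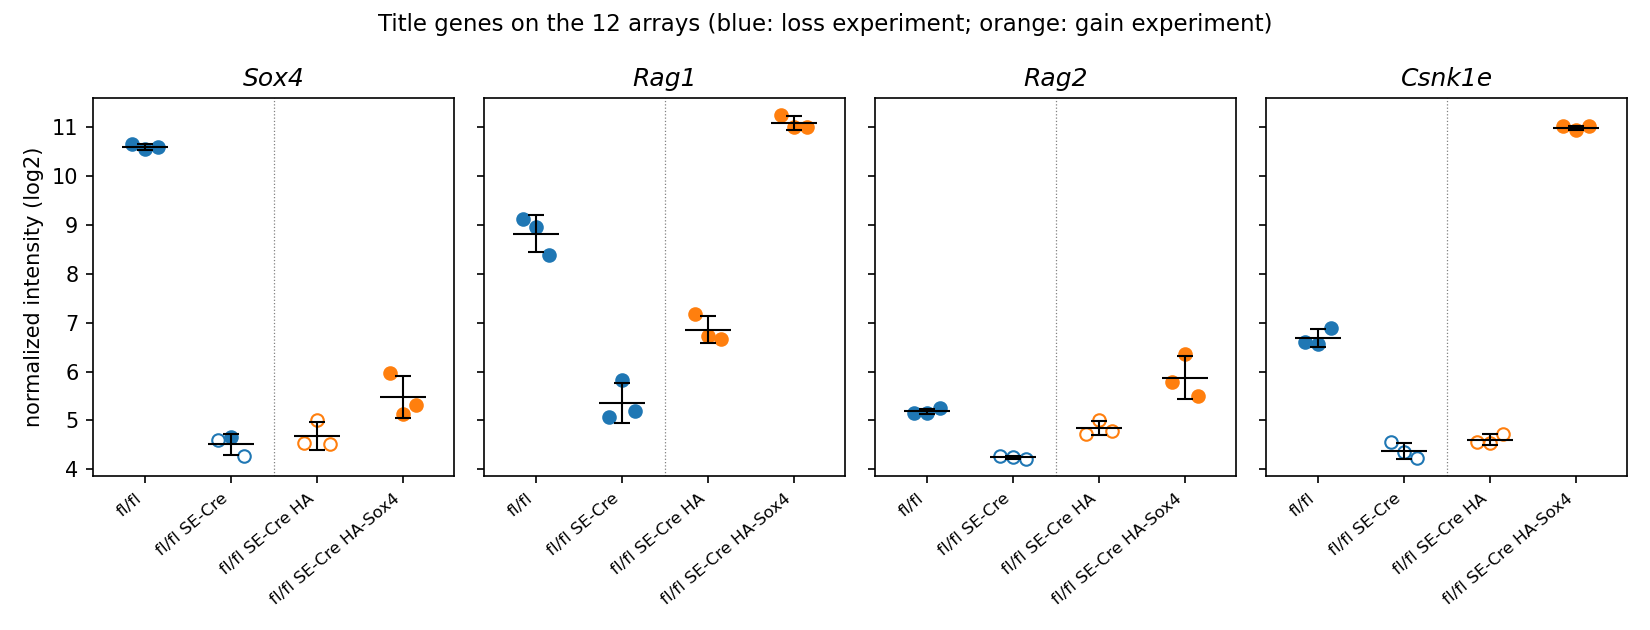
Normalized intensity (log2, vertical axis) of Sox4, Rag1, Rag2 and Csnk1e on each of the 12 arrays by group (horizontal axis), with the mean and SD of 3 arrays in black; open points were not detected, and the 2 experiments were normalized separately. Rag1 lay at 6.86 in HA cells and at 11.09 in HA-Sox4 cells.

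The loss comparison asked which genes differed between Sox4fl/fl and SE-Cre progenitor B cells. Marcksl1, which encodes an actin-binding MARCKS-like protein, was 36.4-fold lower in SE-Cre cells (log2 difference -5.19, SE 0.14, adjusted p = 4.74e-10, all 4 probes). H1f10, a linker histone gene, Casp1, the inflammatory caspase gene, and Auts2, a gene of a Polycomb-associated nuclear protein, were detected on 3 of 3 Sox4fl/fl arrays and on no SE-Cre array. Their signals were at least 19.1-fold, 16.5-fold and 15.2-fold lower. Tnfrsf19, Klk8 and Tmem98, also not detected on any SE-Cre array, fell at least 9.71-fold, 9.18-fold and 8.41-fold. Rnf144a (fitted log2 difference -4.09, detected on 1 of 3 SE-Cre arrays, so its size depends on the background), Arpp21 (-3.58) and Capn2 (-3.41) fell too. In the other direction, the predicted gene Gm5662 rose from no detection on any Sox4fl/fl array to 8.60 ± 0.01 (SD, n = 3), at least 16.5-fold (adjusted p = 9.15e-10). Cacna1h, a T-type calcium channel gene, rose 17.2-fold (log2 difference 4.11, SE 0.16, adjusted p = 8.15e-09). Nav1, detected on 1 of 3 Sox4fl/fl arrays, had a fitted log2 difference of 3.52, the adaptor gene Grb7 of 3.46 and the growth factor gene Igf1 of 2.84. Tph1, which encodes tryptophan hydroxylase, rose at least 7.40-fold, and Apbb1 (3.14), Lrrn3 (3.00), Tspan6 (2.93) and Syndig1l (2.72) rose too. Trbv13-2, a T cell receptor variable segment, rose at least 5.90-fold by its brighter probe, while its other kept probe did not pass the test.

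Across the loss experiment, 2516 of 16454 kept probes (15.3%) passed an adjusted p of 0.05 in limma, 1148 higher and 1368 lower in SE-Cre cells. By gene, 1469 of 8944 changed, 670 up and 799 down, of which 145 and 280 changed at least 2-fold. For 133 of the changed genes a whole group of 3 arrays was not detected. The probe count was 1590, 1536 and 1612 without Sox4fl/fl replicate 1, 2 and 3, more than 1.5 times below the count on 6 arrays, and it was 3978 when all 12 arrays were fitted together. Scaling the arrays to a common median in place of quantile normalization gave 719 higher and 1498 lower probes, so that the share of higher calls went from 45.6% to 32.4%.

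**Figure D2:**
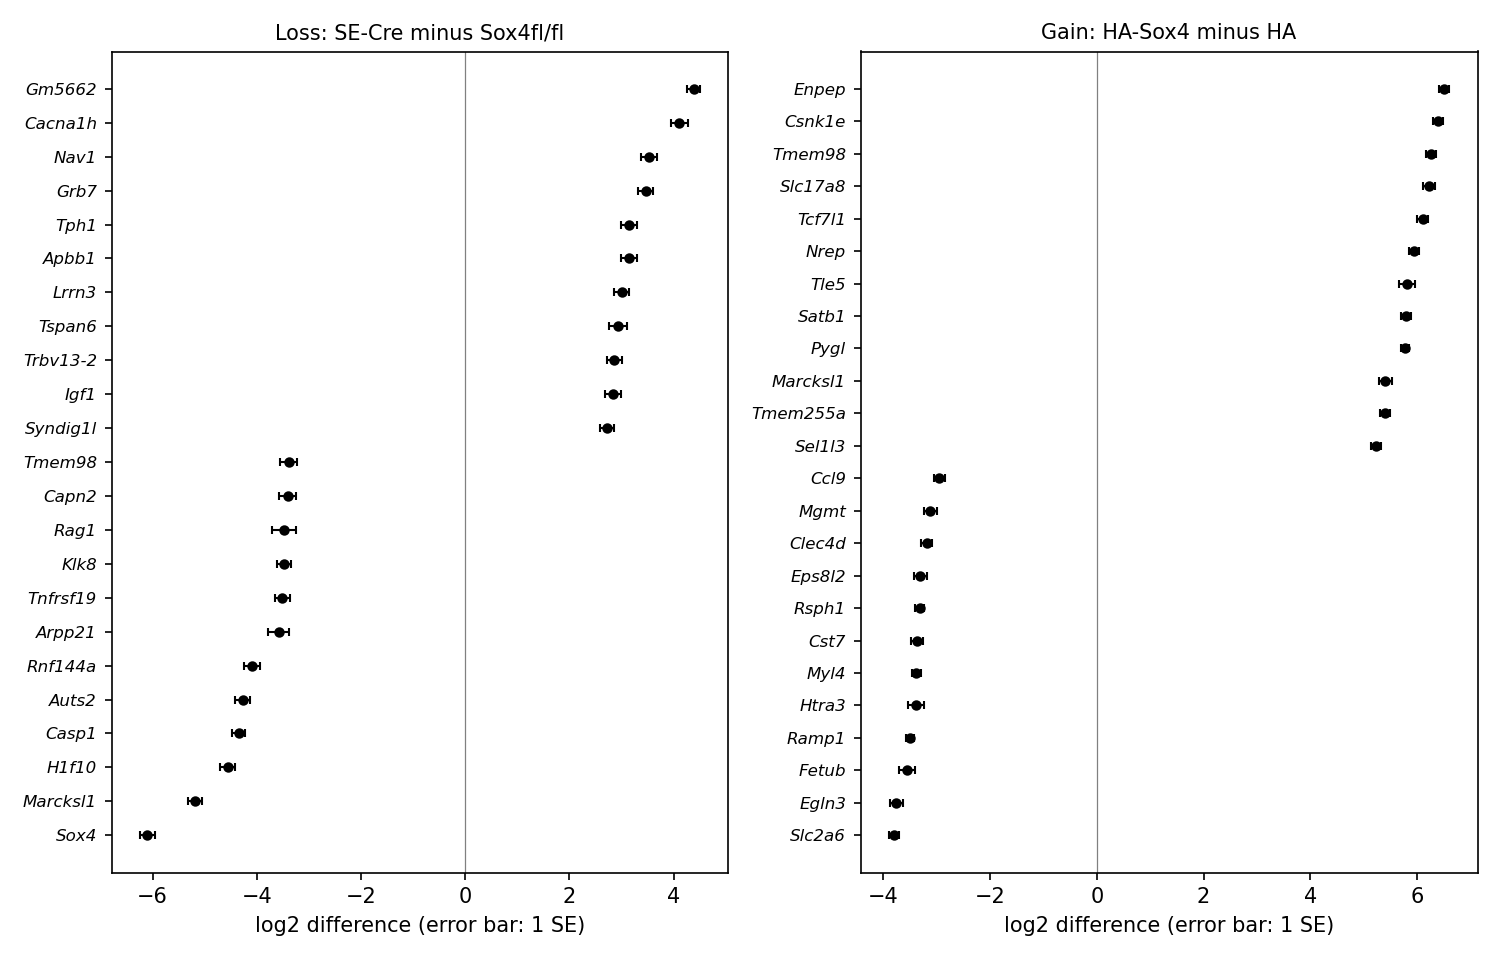
The named genes with the largest fitted rises and falls in each experiment, as the log2 difference between group means (horizontal axis, 3 arrays per group) with an error bar of 1 SE, one gene per line; the difference is a fitted value for genes not detected in a whole group. The difference was -6.10 for Sox4 on loss and 6.51 for Enpep on gain.

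Among B cell genes, members of the recombination machinery fell on loss. Of 8 measured members of the V(D)J recombination list, 4 fell and none rose (4 and 0 when adjusted over the list alone). These were Rag1, Rag2, Dntt (at least 1.44-fold lower) and the ligase gene Lig4 (log2 difference -0.93). The list shifted down in limma's camera test (adjusted p = 0.025, against adjusted p = 0.383 with an estimated correlation). Rag1 and Rag2 are named in the series title, and the list was not tested without them, so its call may rest on them. The Dntt call was lost without background correction (adjusted p = 0.11), with the authors' processed values (0.0913), with no detection filter (0.118) and without SE-Cre replicate 1 (0.0809) or 2 (0.0504). The Lig4 call was lost without background correction (0.0512), with no detection filter (0.188), with all 12 arrays normalized together (0.0653) and without Sox4fl/fl replicate 2 (0.078) or 3 (0.111) or SE-Cre replicate 1 (0.0874). The list's own call was lost without Sox4fl/fl replicate 1 (adjusted p = 0.0838), 2 (0.125) or 3 (0.268), with the authors' processed values (0.0506), without background correction (0.0587) and with probes detected on every array (0.148). Leaving out a Sox4fl/fl array, or requiring detection on every array, also removed Rag2 and Dntt from the list through the detection filter. Of 12 pre-B cell receptor genes, 2 fell and 10 did not pass (adjusted over the list alone, 3 fell; list adjusted p = 0.588). The largest of them was the fall of Blk, a Src-family kinase gene, from 9.08 to 6.31 (log2 difference -2.77, SE 0.18, adjusted p = 4.58e-07). Of 14 B lineage transcription factor genes, 3 fell and 1 rose (7 and 2 adjusted over the list alone; list adjusted p = 0.272): Irf4 (log2 difference -1.08, SE 0.14) and Foxo1 (-0.95, SE 0.17) were among those that fell, and Pax5, the B lineage commitment factor, rose at least 1.63-fold from no detection in Sox4fl/fl cells (adjusted p = 0.0024). Of 10 pro-B and pre-B surface markers, 2 rose and 1 fell, with the same counts over the list alone (list adjusted p = 0.861; median -0.01, mean 0.16). Il2ra, which encodes CD25, a marker of the pre-B stage, rose from 5.02 to 7.09 (log2 difference 2.07, SE 0.17, adjusted p = 3.52e-06). Of 7 mature B cell markers, the chemokine receptor gene Cxcr5 alone passed, with a log2 difference of 1.05 (SE 0.14, adjusted p = 0.000259; also alone over the list; list adjusted p = 0.477; median 0.00, mean 0.18).

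Of 9 measured members of the integrated stress response list, 5 fell on loss and none rose (6 and 0 over the list alone), and the list shifted down (adjusted p = 0.00436, against adjusted p = 0.303 with an estimated correlation). Chac1, which degrades glutathione, fell from 10.31 to 8.63 (log2 difference -1.68, SE 0.17, adjusted p = 2.52e-05), and Asns, the asparagine synthetase gene, fell by 0.86 (SE 0.14, adjusted p = 0.00128, 3 of 3 probes). The other 3 falls were smaller, and each call was lost with an array left out. Trib3 fell by 0.57 (adjusted p = 0.0229), a call lost without Sox4fl/fl replicate 2 (0.0887) or 3 (0.0708) or SE-Cre replicate 1 (0.0823) or 3 (0.0563). Atf4 fell by 0.51 (adjusted p = 0.0462), a call lost with no detection filter (0.0972), with all 12 arrays normalized together (0.0732) and with scaling to a common median (0.0734). It was also lost without Sox4fl/fl replicate 1 (0.18) or 2 (0.137) or SE-Cre replicate 1 (0.105), 2 (0.0792) or 3 (0.102). The replicate number as a block ended the Atf4 call too (adjusted p = 0.0527). Phgdh, outside the naming rule and chosen after its values were seen, fell by 0.45 (adjusted p = 0.0496), a call lost with all 12 arrays normalized together (0.0592) and without any single array (adjusted p between 0.0632 and 0.148). With the replicate number as a block the Phgdh call was lost as well (adjusted p = 0.0632). The list of SoxC genes and their known targets shifted down as well, with 3 of 6 members lower (5 over the list alone; adjusted p = 0.00259, against adjusted p = 0.303 with an estimated correlation). Sox4 itself is a member: without it, a test added after the data were seen, the adjusted p was 0.0701. Sox12, the paralog of Sox4, fell by 1.36 (SE 0.26, adjusted p = 0.00324), a call lost when no detection filter was applied (adjusted p = 0.063).

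Other lists did not pass as a whole on loss. Of 7 Wnt and beta-catenin targets 3 fell (4 fell and 1 rose over the list alone; adjusted p = 0.27), among them Tcf7l2 (log2 difference -0.76, SE 0.15) and Lef1 (-0.99, SE 0.20), the latter not past the threshold with no detection filter (adjusted p = 0.0604). Of 15 genes of casein kinase 1 and the Wnt core, Csnk1e fell and 1 other rose, also over the list alone (list adjusted p = 0.861; median 0.02, mean -0.11). Of 11 p53 targets 3 fell (4 over the list alone; adjusted p = 0.228), with Gadd45a at a log2 difference of -1.45 (SE 0.19). Of 8 BCL2 family genes 2 fell and 1 rose (2 and 2 over the list alone; adjusted p = 0.763), and Bmf, a pro-apoptotic member, was at least 2.60-fold lower. Of 7 cytokine and STAT5 targets 2 fell and 1 rose (3 and 1 over the list alone; adjusted p = 0.161), including Osm (-1.71, SE 0.16) and Cish (-0.75, SE 0.15). Of 14 glycolysis and hypoxia genes 5 rose and 1 fell (6 and 1 over the list alone; adjusted p = 0.103, and 0.0179 with no detection filter), led by Egln3, a prolyl hydroxylase gene of the hypoxia response (log2 difference 1.41, SE 0.19). Of 18 cell cycle genes 1 rose and 1 fell, also over the list alone (adjusted p = 0.41).

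Markers of other cell types were mostly not detected in the loss arrays. Of 5 measured myeloid markers the lysozyme genes Lyz1 (log2 difference 1.75, SE 0.19) and Lyz2 (1.97, SE 0.15) were higher in SE-Cre cells, and the list (2 also over the list alone) had an adjusted p of 0.0718, which passed with a trended robust variance (0.0393) and with scaling to a common median (0.0421). Lyz1 and Lyz2 are near-identical copies, so the probe of each may read the other. Of 5 dendritic cell markers 2 fell (3 over the list alone; adjusted p = 0.0718, which passed with a trended robust variance, 0.0247, and with scaling to a common median, 0.0493), the largest being Ly6d, also a marker of B lineage priming (log2 difference -2.40, SE 0.15). Without Sox4fl/fl replicate 3 (adjusted p = 0.0264) or SE-Cre replicate 2 (0.0387) that list also passed. Of 5 hepatocyte and stromal markers Pecam1 fell by 2.80 (SE 0.16) and Vim by 1.11 (SE 0.18; over the list alone 2 fell and 1 rose; adjusted p = 0.41; median 0.07, mean -0.60), and of 5 T and NK cell markers Klrd1 fell by 1.74 (SE 0.18; 2 of 3 SE-Cre arrays detected it) and 1 other rose (2 rose and 1 fell over the list alone; adjusted p = 0.922; median 0.28, mean -0.14). Of 3 erythroid markers Car2 rose, with a log2 difference of 1.01 (SE 0.16), and the 1 kept mast cell and megakaryocyte marker did not pass; these lists were too short for the list test.

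The gain comparison asked what differed between immortalized SE-Cre cells labelled HA-Sox4 and those labelled HA. The labels do not say whether HA and HA-Sox4 cells came from the same immortalized culture. Differences between cultures therefore cannot be told apart from an effect of HA-Sox4. Enpep, which encodes the aminopeptidase BP-1 of early B cells, rose 91.2-fold, from 5.55 ± 0.10 (SD, n = 3) to 12.06 ± 0.12 (SD, n = 3; log2 difference 6.51, SE 0.10, adjusted p = 8.61e-08). Tmem98, the vesicular glutamate transporter gene Slc17a8, and Tcf7l1, an HMG-box factor of the Wnt pathway, were not detected on any HA array and rose at least 51.8-fold, 50.7-fold and 49.3-fold. Satb1, which encodes a chromatin organizer of lymphoid cells, and Pygl, a glycogen phosphorylase gene, rose at least 46.6-fold and 45.5-fold, Tle5, a Groucho-family corepressor gene, at least 40.3-fold, Nrep at least 37.1-fold and Sel1l3 at least 22.2-fold. Marcksl1 rose 42.4-fold (log2 difference 5.41, SE 0.13) and Tmem255a had a log2 difference of 5.40. Slc2a6, a hexose transporter gene, was 13.9-fold lower in HA-Sox4 cells (log2 difference -3.80, SE 0.10, adjusted p = 4.42e-07), and Egln3 at least 10.3-fold lower. Myl4, a myosin light chain gene, fell from 12.16 to 8.78 (log2 difference -3.38, SE 0.08). Fetub (fitted log2 difference -3.55) and Ramp1 (-3.50), each detected on 1 of 3 HA-Sox4 arrays, and Cst7 (-3.37), detected on 2 of 3, also fell, and their sizes depend on the background. The protease gene Htra3 (-3.39) and Rsph1 (-3.32) fell too, and Eps8l2, the lectin gene Clec4d, the DNA repair gene Mgmt and the chemokine gene Ccl9 were at least 7.70-fold, 7.65-fold, 5.68-fold and 5.31-fold lower, with no detection on any HA-Sox4 array.

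In the gain experiment 7218 of 17504 kept probes (41.2%) passed an adjusted p of 0.05 in limma, 3261 higher and 3957 lower in HA-Sox4 cells. By gene, 4085 of 9249 changed, 1972 up and 2113 down, and of these 703 and 302 changed at least 2-fold. A whole group of 3 arrays was not detected for 409 of the changed genes. A limit of 1.5-fold left 3855 probes. With arrays scaled to a common median, 3196 probes were higher and 2552 lower, so that the share of higher calls went from 45.2% to 55.6%; the median difference of all kept probes was -0.069 with quantile normalization and -0.011 with that scaling.

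Markers of mature B cells rose as a group on gain. Of 7 measured members 6 rose and none fell (also over the list alone), and the list shifted up (adjusted p = 0.00169, against adjusted p = 0.303 with an estimated correlation). Cd74, the invariant chain of MHC class II, rose from 7.62 to 11.62 (SE of the difference 0.09, adjusted p = 3.1e-07), the class II gene H2-Ab1 rose 12.7-fold (log2 difference 3.67, SE 0.10, all 3 probes), and the chemokine receptor gene Ccr7 (2.55, SE 0.22, detected on 2 of 3 HA arrays) and Ltb (2.34, SE 0.23) rose too. Of 11 pro-B and pre-B surface markers 5 rose and 5 fell, also over the list alone (adjusted p = 0.658; median -0.03, mean 0.80). Cd2 and Cd22 rose at least 15.8-fold and 8.48-fold, Kit had a log2 difference of 2.30 (SE 0.15), and Cd93 fell by 0.69 (SE 0.08). Of 9 V(D)J recombination genes 3 rose and 2 fell (3 and 3 over the list alone; adjusted p = 0.861; median -0.10, mean 0.47). Besides Rag1 and Rag2, Dntt, the terminal transferase gene, rose at least 1.68-fold, whereas Lig4 fell by 0.95 (SE 0.25, adjusted p = 0.0217). The Lig4 call was lost without HA replicate 1 (adjusted p = 0.0613) or 2 (0.0508) or HA-Sox4 replicate 2 (0.0704) or 3 (0.0643). Of 12 pre-B cell receptor genes 3 rose and 3 fell, also over the list alone (adjusted p = 0.861). Blk fell from 8.74 to 6.26 (log2 difference -2.48, SE 0.15) and Plcg2 by 1.12 (SE 0.08), while the adaptor gene Blnk rose, with a log2 difference of 1.29 (SE 0.14). Of 15 B lineage transcription factor genes 5 rose and 1 fell, also over the list alone (adjusted p = 0.41), with Bcl11a at 1.09 (SE 0.08), Foxo1 at 1.07 (SE 0.12), Ikzf1 at 0.61 (SE 0.08) and Runx1 at -1.47 (SE 0.11).

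The integrated stress response moved up on gain. Of 10 measured members 6 rose and none fell (also over the list alone), with an adjusted p of 0.025 for the list, against adjusted p = 0.383 with an estimated correlation, and of 0.0506 without HA replicate 2. Chac1 rose 5.11-fold (log2 difference 2.35, SE 0.09), Trib3 had a log2 difference of 2.29 (SE 0.12, 3 of 3 probes), Asns of 0.92 (SE 0.08) and the serine synthesis gene Psat1 of 0.74 (SE 0.08). No other list passed in this experiment. Of 14 glycolysis and hypoxia genes 7 fell and 2 rose (8 and 3 over the list alone; adjusted p = 0.251), with Ldha lower by 0.62 (SE 0.08) and Aldoa by 0.74 (SE 0.09). Of 16 genes of casein kinase 1 and the Wnt core 6 rose and 2 fell (8 and 2 over the list alone; adjusted p = 0.284), among them Fzd7 at 1.46 (SE 0.19) and Lrp5, at least 1.76-fold higher. Of 6 Wnt and beta-catenin targets 2 rose and 2 fell, also over the list alone (adjusted p = 0.984; median -0.22, mean 0.50), with Tcf7l2 at 3.48 (SE 0.14) and Myc at -0.67 (SE 0.08). Of 5 SoxC genes and known targets 1 rose and 2 fell, also over the list alone (adjusted p = 0.984; median 0.16, mean -0.03), and Sox12 fell by 0.92 (SE 0.15; 2 of 3 HA-Sox4 arrays detected it). Of 11 p53 targets 1 rose and 4 fell, also over the list alone (adjusted p = 0.41; median -0.18, mean 0.00), with Gadd45a at 2.88 (SE 0.19). Of 9 BCL2 family genes 3 rose and 4 fell (4 and 4 over the list alone; adjusted p = 0.861; median -0.26, mean 0.29): the pro-apoptotic genes Bmf (at least 5.90-fold) and Bcl2l11 (1.15, SE 0.10) and the anti-apoptotic gene Bcl2l1 (0.83, SE 0.08) rose. Of 9 cytokine and STAT5 targets 3 rose and 1 fell (4 and 1 over the list alone; adjusted p = 0.477), with Cish at 1.44 (SE 0.09) and Pim1 at 0.78 (SE 0.10). Of 18 cell cycle genes 4 rose and 2 fell (4 and 1 over the list alone; adjusted p = 0.477), with Top2a at 0.76 (SE 0.08) and Ccnd2 at -0.63 (SE 0.09).

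Of markers of other cell types in the gain arrays, Lyz1 fell from 9.44 to 6.58 (log2 difference -2.87, SE 0.09) and Lyz2 by 2.52 (SE 0.17). The 6 measured myeloid markers gave 2 rises and 3 falls, also over the list alone (adjusted p = 0.477). The rises were those of Ly6c1 (1.19, SE 0.13) and Cebpb (0.90, SE 0.22, detected on 1 of 3 HA arrays). The other fall was that of Fcgr3, outside the naming rule and chosen after its values were seen, from 5.70 ± 0.57 (SD, n = 3) on 3 of 3 HA arrays to 4.75 with no detection on any HA-Sox4 array (adjusted p = 0.0279 in limma). The Fcgr3 call was lost with no detection filter (adjusted p = 0.052) and without HA-Sox4 replicate 1 (0.065), 2 (0.0876) or 3 (0.0585). Of 5 dendritic cell markers 3 rose and 2 fell, also over the list alone (adjusted p = 0.41), with Ly6d at least 10.5-fold higher and Tcf4 at 1.02 (SE 0.08). Of 5 hepatocyte and stromal markers 3 rose, also over the list alone (adjusted p = 0.0718, and 0.0472 with scaling to a common median): Fn1 at least 4.68-fold, Sparc at least 5.06-fold, and Pecam1 by 0.43 (SE 0.09). Of 5 erythroid markers 2 rose and 1 fell (2 and 2 over the list alone; adjusted p = 0.861; median 0.05, mean -0.14), with Car2 lower by 1.75 (SE 0.12) and Hbb-b2 at least 1.30-fold higher. Of 3 T and NK cell markers Nkg7 rose (2.17, SE 0.14) and Id2 fell by 0.96 (SE 0.15), and of 2 mast cell and megakaryocyte markers Mcpt8, a basophil protease gene, was at least 4.07-fold lower in HA-Sox4 cells; these lists were too short for the list test.

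**Figure D3:**
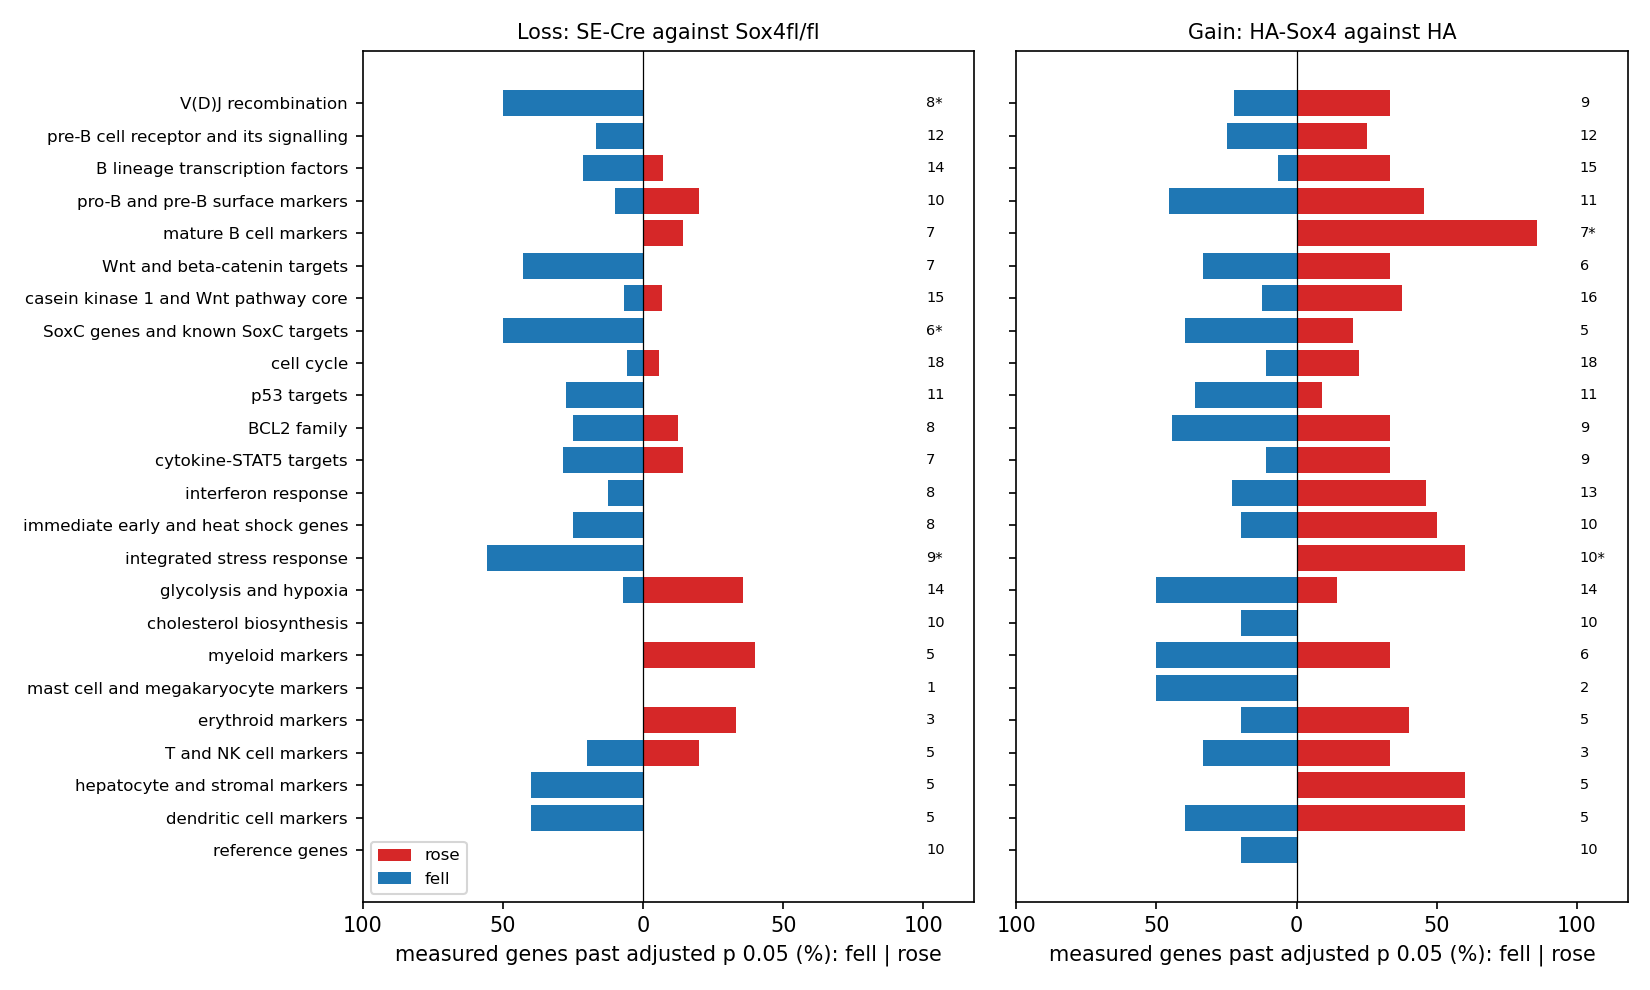
Share of measured genes (%) of each of the 24 lists that passed an adjusted p of 0.05 in the loss (left) and gain (right) experiment, with falls drawn to the left and rises to the right of 0; the number at the right edge counts the measured genes, and a star marks a list past an adjusted p of 0.05 in the list test with a preset correlation. The integrated stress response list had 5 of 9 genes lower on loss and 6 of 10 higher on gain.

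Genes lower in SE-Cre than in Sox4fl/fl cells were often higher in HA-Sox4 than in HA cells. Of 8278 genes measured in both experiments, 940 changed in both, and 767 of them (81.6%) moved in opposite directions. Of these, 460 fell on loss and rose on gain, against 154.5 for independent lists, and 307 rose on loss and fell on gain, against 149.1. The genes that moved in the same direction in both numbered 173, of which 84 fell against 181.9 for independent lists and 89 rose against 126.6. Among the 940 genes the direction on loss and that on gain were associated (Fisher's exact test, p = 1.67e-85, with genes as units, which are not independent). Marcksl1, Auts2, Rag1, Tmem98, Emp1, Tmem176b, the Hippo pathway factor gene Tead1, Maged1, Snx10 and the cell polarity gene Pard6g were those down on loss and up on gain whose smaller change of the 2 was largest. For Emp1 the log2 differences were -3.22 and 3.87, and for Maged1 -2.90 and 3.50. Up on loss and down on gain were Ccl9, Htra3, Lyz1, Lyz2, Slc5a9, Trmt9b, Col26a1, Zan, Gm5111 and 0610040J01Rik. Ccl9 had a log2 difference of 1.57 (SE 0.14) on loss and was at least 5.31-fold lower on gain. Without Sox4fl/fl replicate 2 the opposite group held 503 genes. Across the 8278 genes, which are not independent replicates, the log2 differences on loss and gain had a Pearson correlation of -0.40 and a Spearman correlation of -0.34.

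**Figure D4:**
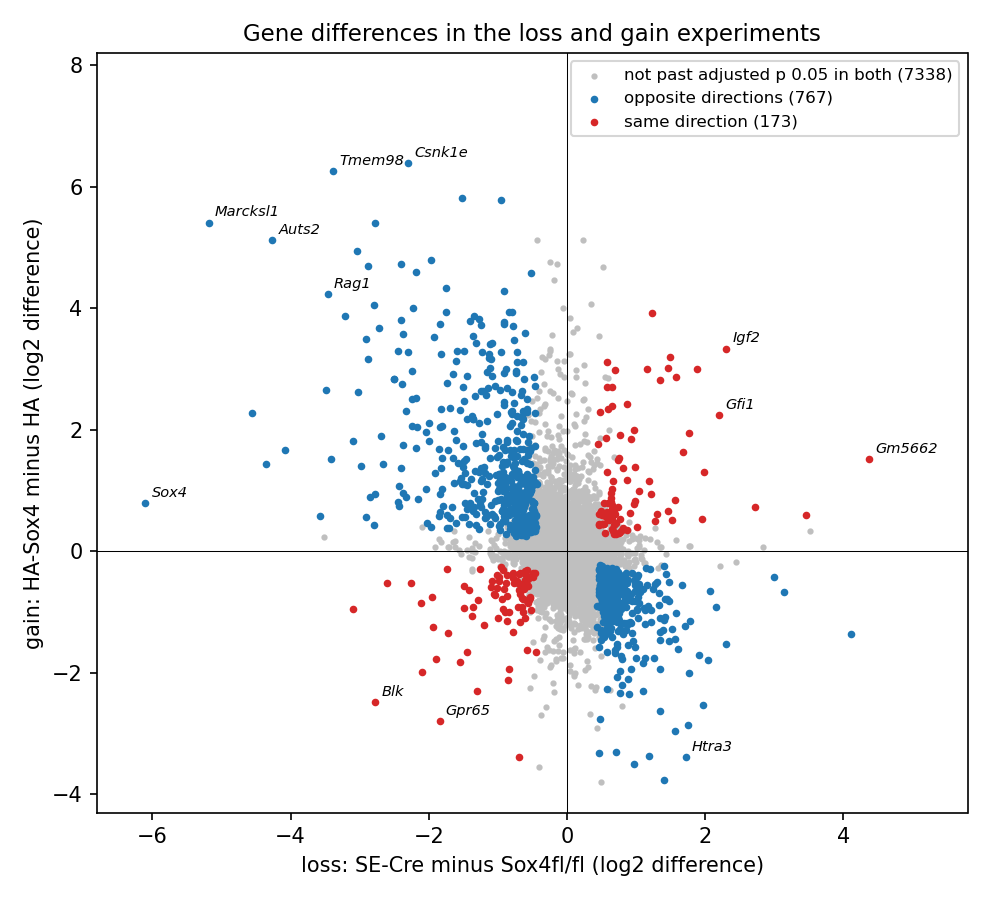
Log2 difference on loss (horizontal axis) against that on gain (vertical axis) for the 8278 genes measured in both experiments, one point per gene; blue points passed an adjusted p of 0.05 in both experiments with opposite signs and red points with the same sign. The 767 opposite genes outnumber the 173 with the same sign.

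Some genes moved in the same direction in both experiments. Blk, the proton-sensing receptor gene Gpr65, Smim41, Gfi1b, Calhm6, Scin, Rpl3l, Grn, 1700048O20Rik and Map2 fell in both, with Gpr65 at least 3.27-fold lower on loss and at a log2 difference of -2.80 on gain, and Gfi1b, a transcriptional repressor gene, at -1.30 and -2.30. Igf2, which encodes a fetal growth factor, rose 4.94-fold on loss (log2 difference 2.30, SE 0.14) and 10.1-fold on gain (3.33, SE 0.14, detected on 2 of 3 HA arrays). Gfi1, the paralog of Gfi1b, rose by a log2 difference of 2.20 (SE 0.17) on loss and 2.25 (SE 0.09) on gain. Acer3, Dgcr6, Foxc1, Gm5662, St6galnac3, Zcchc18, Asb2 and Bhlhe40 also rose in both. In a fit of all 12 arrays, the HA-Sox4 minus HA difference was compared with the Sox4fl/fl minus SE-Cre difference, and 3456 of 19663 probes passed an adjusted p of 0.05 in limma: it was higher in the gain experiment for 1759 and lower for 1697. The experiments also differed in immortalization, so that a difference between them cannot be assigned to Sox4 alone.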

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

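The tests of false calls, of differences kept after scaling, of probes near background, of a smaller spread and of myeloid cells were chosen after the result, or values close to it, had been seen; the tests of calls kept after scaling, of the brightest probes and of regrouped samples were set before.

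Named genes came up for a closer look where the HA-Sox4 minus HA and the Sox4fl/fl minus SE-Cre differences (log2) differed between the experiments in the fit of 12 arrays, past an adjusted p of 0.05. The values are the former minus the latter. Only the series title genes and genes named for a change in both experiments were looked at, so the number of such genes has no meaning of its own. For genes that moved the same way in both experiments these differences have opposite signs by construction. For those that rose in both, the difference was 6.22 for Gm5662, 5.53 for Igf2, 4.84 for Acer3, 4.64 for Zcchc18, 4.48 for Gfi1, 4.26 for St6galnac3, 4.22 for Asb2, 4.10 for Bhlhe40, 3.59 for Dgcr6 and 3.48 for Foxc1. For those that fell in both, it was -5.23 for Blk, -5.01 for Gpr65, -4.09 for Smim41, -3.91 for Calhm6, -3.74 for Gfi1b, -3.30 for Grn, -3.29 for Scin, -3.15 for 1700048O20Rik, -2.91 for Rpl3l and -2.43 for Map2. Of the genes that moved in opposite directions, Tmem98 differed by 2.01, Tmem176b by 1.5, Tead1 by 1.17, Trmt9b by 0.97, 0610040J01Rik by 0.83, Emp1 by 0.57, Ccl9 by -1.02, Lyz1 by -1.08 and Htra3 by -1.54. Csnk1e differed by 3.26 and Sox4 by -5.91, the latter with the unknown position of its probe. For Csnk1e, Sox4, Gm5662, Tmem98, Asb2, St6galnac3, Gpr65, Tead1, Ccl9 and 0610040J01Rik a group in either experiment was not detected on any array, so these values are fitted at the background and their sizes were not measured.

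The first pattern is the 173 genes that changed the same way on loss and on gain. Of these, 84 fell and 89 rose, against 181.9 and 126.6 for independent lists. They are thus fewer than changes unrelated between the experiments would give, so their number alone calls for no common cause. The 0.05 limit on false calls would give 30.6 such genes, which false calls do not reach as the whole cause, and 74.6% of the genes were detected on all 12 arrays, against 76% of the opposite genes, which argues against probes near background as the whole cause; a first form of that test, detection in the brighter group, was dropped because the filter fixed its outcome. After scaling to a common median 69.9% (121 genes) were called alike, against 76.5% of the opposite genes, below the bound set beforehand to exclude a shift from the quantile normalization. However, 100% of the 173 genes kept both directions and at least 0.5 of both log2 differences. So did 100% of the 767 opposite genes, so this later test does not set the 2 classes apart. Scaling moved the differences of the 173 genes by a median of 0.08 on loss and 0.08 on gain, against median sizes of 0.77 and 0.76. These small moves argue against the choice between these 2 normalizations as the whole cause. A part in the other 52 calls stays open. Immortalization separates the experiments completely, so a different action of Sox4 in the 2 kinds of cells stays open and untested. An effect of SE-Cre itself, which no group separates from loss of Sox4 in the loss experiment, stays open and untested too. So do differences between HA and HA-Sox4 cultures other than HA-Sox4.

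The second pattern is the larger number of changed probes on gain, 7218 against 2516. Without regard to p, 1267 of 15057 probes differed at least 2-fold on gain and 585 on loss, a ratio of 2.17, which argues against a smaller spread between the gain arrays as the whole cause. Among the 3765 brightest probes the ratio was 1.94 (136 against 70), which argues against compression of dim probes in the loss arrays as the whole cause. It was below the 2.17 of all these probes, so a part stays open. With 12 arrays normalized and fitted together, and so sharing a spread, 3978 probes changed on loss and 5717 on gain, a ratio of 1.44. With the same normalization and separate fits they numbered 2186 and 7381, a ratio of 3.38. Much of the excess in calls thus went with the separate fits, in which each experiment kept its own spread. Immortalization, time without Sox4, and differences between HA and HA-Sox4 cultures other than HA-Sox4 were not tested.

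The third pattern is the higher signal of Lyz1 and Lyz2 in SE-Cre and in HA cells. Myeloid cells in the SE-Cre samples would bring their other transcripts. Csf1r was detected on 2 SE-Cre arrays and 1 Sox4fl/fl array, and Mpo on 1 and 0. Prtn3 and Ly6c1 were detected on 1 array of each group, and Ngp and Fcgr3 on 0 SE-Cre arrays and 1 Sox4fl/fl array. However, of 16 other myeloid markers only 2, Cebpb and Csf2ra, were detected on all 3 SE-Cre arrays, and Elane, S100a8, S100a9, Cd14, Itgam, Ctsg, Camp and Cebpa were detected on 0. For myeloid cells in the HA samples it was 3 of 16, with 0 arrays for the same 8 genes; of the 4 tested there, Fcgr3 was higher in HA cells, as Lyz was (5.70 against 4.75, adjusted p = 0.0279), Ly6c1 and Cebpb were lower, and Csf2ra did not pass (adjusted p = 0.254). This argues against myeloid cells that carry these transcripts as the whole cause, as far as the probes work, which was not tested; an earlier form of the test, the count of markers past the threshold, was dropped because only 3 markers on loss and 4 on gain were tested. Other cells that carry Lyz without these transcripts, and a change inside the B cells, stay open, and some of these markers lie outside the naming rule. Genes outside the marker list were not weighed. Among them, the chemokine gene Ccl9 was higher in SE-Cre and in HA cells, as Lyz was. The lectin gene Clec4d was higher in HA than in HA-Sox4 cells.

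All regroupings of the samples into 3 and 3 within experiments were used to test whether any grouping gives such results. For changed probes 1 of 10 splits, the real split, gave as many on loss (2516, highest other 0) and 1 of 10 on gain (7218, highest other 0), and for lists 1 of 10 on loss (3, highest other 1) and 1 of 10 on gain (2, highest other 1); 10 splits are too few for a share under 0.05. Of 100 pairs of splits 1 gave as many opposite genes (767, highest other 0), which decides nothing more, since no other split gave any call. Of the same pairs 1 gave as large a correlation (-0.40, largest other 0.37 in size) and 1 as many probes that differed between the experiments (3456, highest other 2660). For the correlation this argues only weakly against a random grouping of samples, since the other pair came within the jackknife SD over arrays of 0.0466. For the probe count it argues against a random grouping, within the limit given next. The 2660 came from a pair that kept the real gain groups. Without them the highest was 503, and with neither experiment's real groups it was 0. The result for the probe count thus rests mostly on the gain groups, which are 1 of 10 splits.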

How the results depend on the processing

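The scaling of each named gene and the SoxC list without Sox4 were added after results had been seen. Of 4719 values for 292 named gene results, 292 as reported, 4201 kept direction and side of the threshold, 159 lost the call, 67 gained it and 0 reversed. The Sox4 rise on gain stayed at 0.79 but missed the threshold with no detection filter (adjusted p = 0.0615; more probes were tested) and ranged from 0.71 to 0.98 with an HA array left out; without any HA-Sox4 array, or with probes detected on every array, its probe was not kept. Changed probes on loss numbered 3978 with 12 arrays fitted together and 1536 to 1996 with fewer arrays. With 12 arrays normalized together but fitted separately they numbered 2186, so the joint fit and not that normalization raised the count. On gain they numbered 3855 at a limit of 1.5-fold and 5468 to 6202 with an array left out. Lists called on loss numbered 1 with probes detected on every array (fewer genes tested), 5 with trend and robust, 5 with scaling to a common median, 0 with an estimated correlation, 2 without Sox4 in the SoxC list and 2 to 4 with an array left out. Lists called on gain numbered 1 with probes detected on every array, 0 with an estimated correlation and 1 to 2 with an array left out. Opposite genes numbered 503 to 714 with an array left out. The correlation was -0.331 with no detection filter, against -0.404 (jackknife SD 0.0466). Too few members of the mature B cell and SoxC lists were detected on every array for a test. With the replicate number as a replicate block, 2387 probes changed on loss and 6448 on gain, and Sox4 on gain was 0.79 (adjusted p = 0.0614); same-numbered samples correlated between -0.023 and 0.041 and did not always correlate best with their own number, so the numbers were not taken as pairs. Other causes were not tested. Signal over background limits dim probes such as Sox4 on gain and Rag2.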

Other observations

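Of the interferon response genes, Rsad2, the viperin gene, rose on gain from 7.37 to 8.99 (log2 difference 1.62, SE 0.09, adjusted p = 1.63e-05), and Ifit3 (1.24, SE 0.07), Ifit2 (1.11, SE 0.12) and Oasl2 (1.00, SE 0.10) rose too. Of 13 measured members 6 rose and 3 fell (6 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.371). On loss, 1 of 8 members, Bst2, fell (log2 difference -0.71, detected on 1 of 3 SE-Cre arrays, adjusted p = 0.0445, and up to 0.213 under settings that ended the call; 0 over the list alone; list adjusted p = 0.861; median 0.01, mean -0.06), and Ifit3 was at 4.69 and 4.83.

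Of the immediate early genes, Egr1, a growth-responsive zinc finger gene, changed in both experiments. In limma it fell by 0.99 (SE 0.17, adjusted p = 0.00195) on loss and rose on gain, with a log2 difference of 1.27 (SE 0.08, adjusted p = 2.48e-05). Fos fell by 0.97 on loss (SE 0.15). On gain the phosphatase gene Dusp1 (1.10, SE 0.09) and Atf3 (at least 1.46-fold) rose, and Junb fell by 1.20 (SE 0.08). Of 8 immediate early and heat shock genes 2 fell on loss (also over the list alone; list adjusted p = 0.477), and of 10 on gain 5 rose and 2 fell (also over the list alone; adjusted p = 0.272).

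Cholesterol biosynthesis and reference genes moved little. None of 10 cholesterol genes passed on loss (adjusted p = 0.861), and 2 of 10 fell on gain (also over the list alone; adjusted p = 0.861), with Lss lower by 0.67 (SE 0.11). None of 10 reference genes passed on loss (adjusted p = 0.861), and on gain 2 fell (also over the list alone; adjusted p = 0.848): Rplp0 by 0.58 (SE 0.08) and Gusb by 0.58 (SE 0.09).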
